A study of Gossypium hirsutum with 9 samples.

How the data were processed

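The samples were ovules of upland cotton (Gossypium hirsutum, strain TM-1) kept in culture on 50, 150 or 300 mM glucose for 5 days, with 3 RNA sequencing libraries per concentration. Per the labels, total RNA was extracted from the cultured ovules and made into Illumina libraries with a NEBNext Ultra kit. HISAT2 and featureCounts 1.5.0-p3 are the programs named for alignment and read counting, per the submitters' processing notes. The genome build, the annotation, the strand setting and the treatment of reads shared between near-identical genes are not given in the sources used here. The libraries were assigned to groups by the glucose concentration in their labels. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be in part technical.

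The authors deposited FPKM values (read counts divided by gene length and by a library-size term), with 80970 rows for each library. Of these rows, 75376 carry a Gohir ID and 5594 are loci numbered outside that naming. The definition of the library-size term is not given in the sources used here. Within a gene, the FPKM values of different libraries stood in whole-number ratios after a factor for each library, so the whole reads behind them could be recovered. All 68279 rows above 0 in at least 1 library gave whole reads within a tolerance of 0.001, and on simulated values 99.8% of 19894 rows were recovered exactly. Lengths under 60000 bases were tried, so a row above 0 in few libraries can meet the tolerance at a wrong length. The recovered totals ranged from 17803705 to 19140279 reads per library. The library-size term in the deposited values was 0.984 to 1.1 times the recovered total, with a mean of 0.993 ± 0.0106 (SD, n = 3) at 50 mM, 1.03 ± 0.0236 at 150 mM and 1.09 ± 0.0121 at 300 mM. It therefore was not the recovered total. Divided by median-ratio size factors computed from the recovered reads, it ranged from 18.9 to 19.4 in units of 1000000 reads over the 9 libraries. Of the gene lengths recovered in rows with at least 100 reads over all libraries, 95.5% of those with Gohir IDs were divisible by 3. The lengths of Gohir IDs are called coding lengths.

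In a gene of 1000 bases 1 read corresponds to an FPKM of 0.05 to 0.0545, so counting error at this depth is small for all but low or short genes. In short genes an FPKM above the filter can rest on few reads. For Gohir.D12G274150.v2.1, of 135 bases, an FPKM of 1.98 in replicate 1 at 50 mM was 5 reads. The reads carry no molecular identifiers in these tables, so intervals from read numbers cover counting error only. No pair of libraries held identical values. Between libraries of the same group the chi-square per degree of freedom was 4.68 to 18.7, so no pair agreed within sampling noise, as the same library deposited again would. This does not tell separate cultures from repeat preparations of the same culture.

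Because the values are FPKM, the test planned for count tables was not used. The alternative fixed for values without counts was used in its place: log2(FPKM + 0.5) was fitted with limma 3.58.1 (empirical Bayes with a mean trend and robust variance, statmod 1.5.0, R 4.3.3) on genes with an FPKM of at least 1 in at least 3 libraries. All 9 libraries entered the same fit, with the glucose concentration as the only term. Two-sided tests compared 150 with 50 mM, 300 with 150 mM and 300 with 50 mM, and an F test covered the 3 concentrations together. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and 50988 genes were tested. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes near 0. Genes passing the F test were sorted by the order of the 3 group means.

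On simulated reads with 200 changed genes, the fit recovered 73.1% of genes changed 2-fold and 92.4% of genes changed 4-fold for 150 against 50 mM, among 50066 genes tested. The shares were 68.7% and 90.9% for 300 against 150 mM among 50105 genes, and 71.6% and 89.4% for 300 against 50 mM among 50101 genes. Genes changed 1.5-fold were recovered in 4.48%, 7.46% and 7.46% of cases in the same order. Among the simulated calls, 1.74%, 3.48% and 7.44% were false (2 of 115, 4 of 115 and 9 of 121 calls). In the data 14924, 3113 and 16456 genes passed in the same order, many more than the 200 changed in the simulation. The Benjamini-Hochberg threshold is stricter where few genes change. The simulated shares therefore do not give the share of changed genes recovered, at 1.5-fold or above, or of false calls in the data.

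None of the file IDs matched the gene table supplied for the species, which lists 99454 genes (0 matches), and the files do not pair IDs with names or descriptions. The 30 gene lists fixed beforehand, among them brassinosteroid synthesis and signalling, wall-loosening enzymes, sugar transporters and osmotic stress, select genes by description and were therefore not tested. By the rule set for this case, the text names the 2 higher and the 2 lower IDs of largest fold per comparison. Each had to pass the test, reach a mean FPKM of at least 5 in the higher group and show no overlap between the 2 groups. Subgenome and chromosome were read from the ID itself (A or D and a number), and the order of genes on a chromosome from the number that follows, on the assumption that the IDs are numbered along the chromosomes. Calls on A and D chromosomes were compared with Fisher's exact test, as were calls on each of the 26 chromosomes against the rest.

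The designs, the rule for named genes and the main alternatives were fixed before the data were examined. These alternatives were other pseudocounts, other filters on low values, median-ratio and upper-quartile scaling, a fit of only the groups compared, a replicate block, stricter thresholds and leaving out each library. Chosen after seeing the data were limma-voom on the recovered reads, scaling each library to its recovered reads, and the reading of results without replicate 1 of the 300 mM group, alone and together with that scaling. The checks of gene structure used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.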

Results

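Transcript levels were measured by RNA sequencing in cotton ovules cultured for 5 days on 50, 150 or 300 mM glucose. Cotton fibres are single cells that grow out of the ovule surface, and ovules in culture depend on the sugar of the medium. The series asks how glucose bears on fibre elongation and on brassinosteroid, a steroid hormone of plants. Each concentration had 3 libraries, with 18330981 to 19140279 recovered reads per library at 50 mM, 18318653 to 18881646 at 150 mM and 17803705 to 18585378 at 300 mM. An FPKM of at least 1 was reached by 47826 to 48933 genes per library. The 10 most abundant genes took 1.67% to 2.41% of the reads of a library. The RNA came from ovules with no separation of fibre from other ovule cells stated in the labels, so each value describes the tissue as a whole. The samples include no osmotic control. Effects of glucose as a sugar, of the osmolarity of the medium and of a changed share of cell types cannot be told apart.

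The libraries separated by glucose concentration. The first principal component held 51.2% of the variance and set the 50 mM libraries, at -94.1 to -110.1, apart from the other 6, at 28.6 to 88.5. The second held 21.2% and separated 150 mM, at 46.0 to 66.1, from 300 mM. Replicate 1 of the 300 mM group stood apart from its group on this axis, at -23.6 against -73.4 and -70.8. Its correlation across genes was 0.953 and 0.945 with the other libraries at 300 mM, and 0.953, 0.929 and 0.958 with those at 150 mM. Within groups the correlations were 0.972 to 0.979 at 50 mM, 0.96 to 0.975 at 150 mM and 0.945 to 0.959 at 300 mM. Between 50 and 300 mM they were 0.847 to 0.904. These correlations are over genes, which are not independent replicates.

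**Figure D1:**
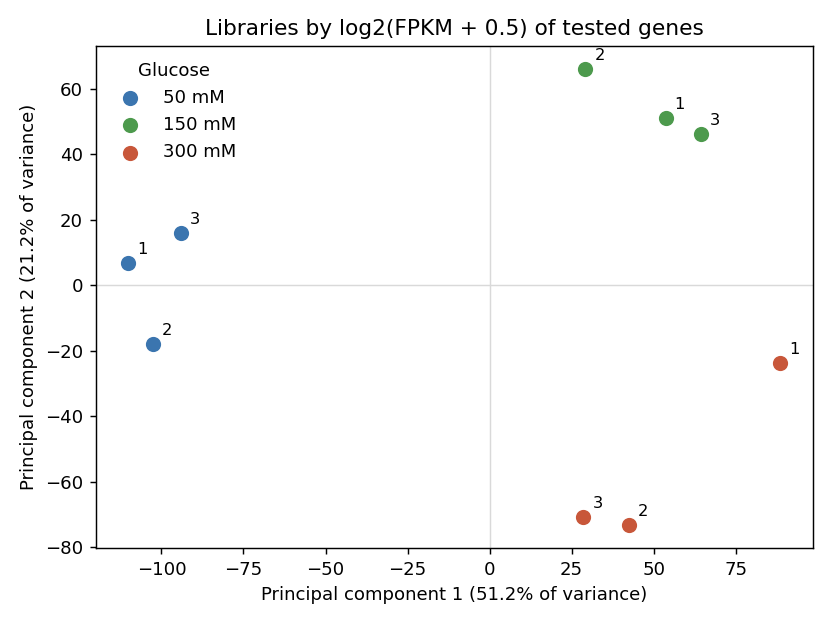
Principal components of log2(FPKM + 0.5) over the 50988 tested genes, 1 point per library, coloured by glucose concentration and numbered by replicate. The 50 mM libraries lie between -110.1 and -94.1 on component 1, and replicate 1 at 300 mM lies at -23.6 on component 2, against -73.4 and -70.8 for the other libraries of its group.

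Between 50 and 150 mM glucose, the levels of 14924 of 50988 tested genes (29.3%) changed, of which 8145 rose and 6779 fell (54.6% higher). The split depended on the scaling. With each library scaled to its recovered reads 9026 rose and 5988 fell (60.1% higher). With median-ratio scaling 7718 rose and 7183 fell (51.8% higher). The median log2 change was 0.89 among the genes that rose and -0.84 among those that fell. A change of at least 2-fold was reached by 3457 rising and 2685 falling genes, and of at least 8-fold by 62 rising and 133 falling genes. Gohir.D11G300400.v2.1 rose from an FPKM of 7.28 ± 6.15 to 371 ± 83.9 (mean ± SD, n = 3), a log2 change of 6.14 (SE 0.802, limma adjusted p = 0.000736). The log2 change was 5.07 without replicate 1 of the 50 mM group and 6.82 without replicate 2. Gohir.A05G071000.v2.1 rose from 0.554 ± 0.315 to 46.2 ± 9.73, a log2 change of 5.50 (SE 0.433, limma adjusted p = 0.000122). Its 50 mM libraries held 1, 4 and 3 reads.

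Gohir.D09G146800.v2.1 was the gene of largest fall at 150 mM under the naming rule. Its FPKM went from 121.8 ± 30.9 to 0.621 ± 0.493 (n = 3), a log2 change of -6.86 (SE 0.412, limma adjusted p = 6.89e-05). Gohir.D06G007100.v2.1 fell from 499.8 ± 168 to 13.3 ± 15.6, a log2 change of -5.76 (SE 0.983, limma adjusted p = 0.00248). That change was -5.15 without replicate 1 and -6.68 without replicate 2 of the 150 mM group. The files do not pair these IDs with names or descriptions, so the function of the genes is not given here. The values of the 2 groups did not overlap in 48.9% of tested genes, where chance gives 10%. At an unadjusted p under 0.05 the count was 20940.

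Between 150 and 300 mM glucose, 3113 genes changed (6.11%), and most of these fell. There were 2445 genes lower and 668 higher at 300 mM, so that 21.5% of the calls were higher. With each library scaled to its recovered reads, a setting chosen after seeing the data, 1065 were higher and 1991 lower (34.9% higher). The median log2 change was -1.17 among the genes that fell and 0.99 among those that rose, and 1523 falling and 330 rising genes changed at least 2-fold. Gohir.A09G106800.v2.1 fell from an FPKM of 17.4 ± 8.25 to 0.387 ± 0.376 (n = 3), a log2 change of -4.33 (SE 0.416, limma adjusted p = 0.00172).

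Gohir.D01G000600.v2.1 fell at 300 mM from 10.1 ± 5.27 to 0.0781 ± 0.135 (n = 3), a log2 change of -4.09 (SE 0.378, limma adjusted p = 0.00172), with 4 reads in 1 of the 300 mM libraries and 0 in the others. The largest rises on the log2(FPKM + 0.5) scale under the naming rule belonged to an ID on chromosome A12 and an ID on chromosome D12. Gohir.A12G273450.v2.1 went from 0.334 ± 0.332 to 57.6 ± 37.3, a log2 change of 5.90 (SE 0.639, limma adjusted p = 0.00208), or of 6.63 without replicate 3 of the 300 mM group. It had 3 reads in the 150 mM libraries together and 523 at 300 mM, a ratio of 168.3 with a 95% counting interval of 57.3 to 818.5 (exact conditional binomial). Gohir.D12G274150.v2.1 went from 0.631 ± 0.576, with 3, 0 and 2 reads in the 150 mM libraries, to 58.3 ± 32.1, a log2 change of 5.66 (SE 0.599, limma adjusted p = 0.00201). Neither rise passed with limma-voom on the recovered reads, although the fitted log2 changes there were not smaller, at 6.78 for Gohir.A12G273450.v2.1 (limma adjusted p = 0.221) and 6.30 for Gohir.D12G274150.v2.1 (limma adjusted p = 0.0985). Under the other alternatives the limma adjusted p was 0.00186 to 0.0111 for the A12 ID and 0.0016 to 0.0111 for the D12 ID. Both IDs had lower values at 150 than at 50 mM, where their FPKM was 2.8 ± 1.94 and 3.69 ± 2.6. For Gohir.D12G274150.v2.1 that first step passed the test as a fall (log2 change -1.89, limma adjusted p = 0.0404), and for Gohir.A12G273450.v2.1 it did not (-1.89, limma adjusted p = 0.0509).

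The size of the 300 against 150 mM response depended on the libraries used. Without replicate 1 of the 300 mM group 4395 genes were called, 30.8% of them higher, and with scaling to recovered reads as well 4598 genes were called, 44.2% of them higher. The count was 1547 (12.99% higher) without replicate 2 and 2036 (16.1%) without replicate 3 of the 300 mM group. Without replicates 1, 2 and 3 of the 150 mM group it was 1708 (13.8% higher), 1764 (18.5%) and 2125 (18.1%). A fit of the 150 and 300 mM libraries alone called 2002 genes. At an unadjusted p under 0.05 there were 10022 genes, and the groups did not overlap in 23.0% of genes, where chance gives 10%.

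**Figure D2:**
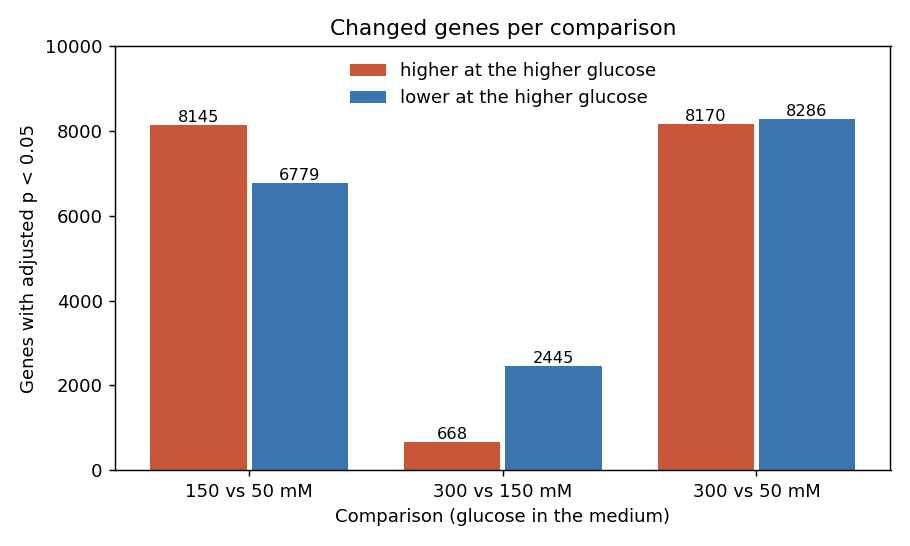
Number of genes (of 50988 tested) past a limma adjusted p of 0.05 in each comparison, with red bars for genes higher and blue bars for genes lower at the higher glucose concentration. From 150 to 300 mM 668 genes were higher and 2445 lower, fewer than the 8145 and 6779 of the step from 50 to 150 mM.

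Across the whole range, 300 against 50 mM, 16456 genes changed (32.3%), with 8170 higher and 8286 lower. With each library scaled to its recovered reads the split was 11467 higher and 6331 lower (64.4% higher against 49.7%), and the median log2 change of all tested genes moved from 0.0077 to 0.128. The median log2 change was 0.78 among rising and -0.89 among falling genes, and 2807 rising and 3523 falling genes changed at least 2-fold. Gohir.D11G300400.v2.1 had the largest rise here as well on the log2(FPKM + 0.5) scale, reaching an FPKM of 783 ± 550 (n = 3), a log2 change of 7.01 (SE 0.802, limma adjusted p = 0.000316). Without replicates 1 and 2 of the 50 mM group, left out in turn, the change was 5.95 and 7.70. With limma-voom on the recovered reads it was 7.29, below the 8.37 of Gohir.A03G100200.v2.1, so the order of these rises depended on the scale. The difference of Gohir.D11G300400.v2.1 between 150 and 300 mM did not pass (log2 change 0.88, limma adjusted p = 0.616).

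Gohir.A03G100200.v2.1 increased at each step. It had 2 reads in the 50 mM libraries together, an FPKM of 2.01 ± 0.742 (n = 3) at 150 mM and of 20.5 ± 8.63 at 300 mM. The log2 change was 2.16 for the first step (limma adjusted p = 0.00107) and 3.03 for the second (limma adjusted p = 0.00181). From 50 to 300 mM it was 5.20 (SE 0.308, limma adjusted p = 2.16e-05), and the ratio of read rates was 445.2 with a 95% counting interval of 122.9 to 3682.

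Gohir.D09G146800.v2.1 remained low at 300 mM, at an FPKM of 0.321 ± 0.383 (n = 3), a log2 change of -7.29 from 50 mM (SE 0.412, limma adjusted p = 2.13e-05). Gohir.A03G204000.v2.1 fell at each step, from 52.7 ± 8.02 to 5.92 ± 3.71 and 0.401 ± 0.459, a log2 change of -6.0 from 50 to 300 mM (SE 0.529, limma adjusted p = 0.000102). The steps were -3.29 (limma adjusted p = 0.00187) and -2.71 (limma adjusted p = 0.0169). The groups at 50 and 300 mM did not overlap in 46.3% of genes, where chance gives 10%.

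**Figure D3:**
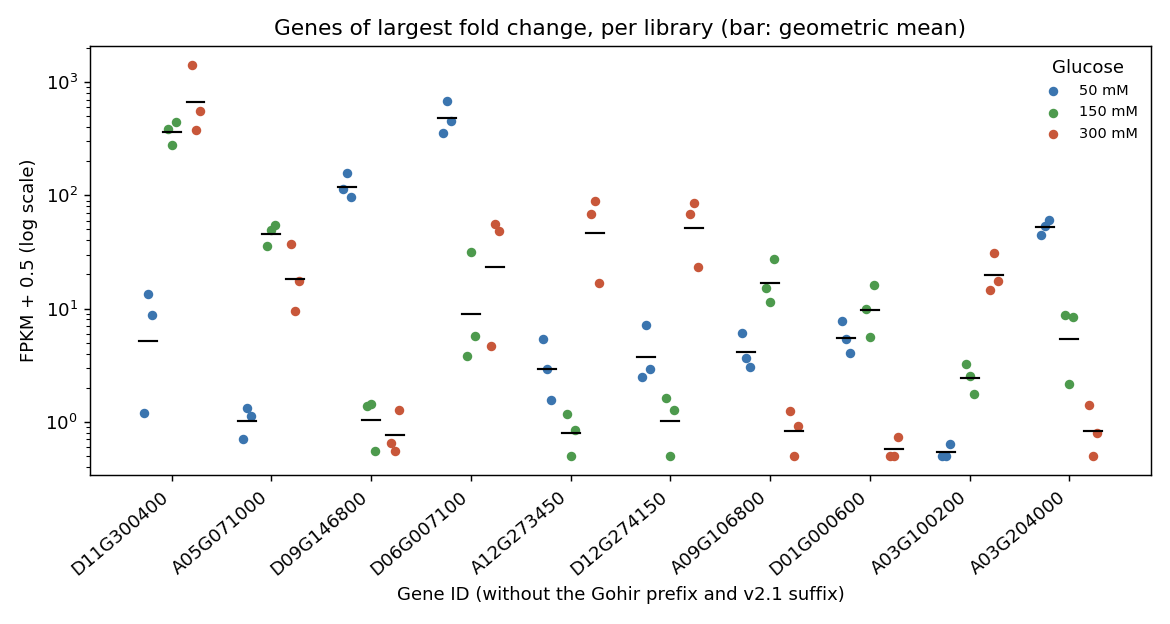
FPKM + 0.5 on a log axis for the 10 IDs named by the rule, 1 point per library, coloured by glucose concentration, with a bar at the geometric mean of the 3 libraries. Gohir.D09G146800.v2.1 falls from a mean FPKM of 121.8 at 50 mM to 0.621 at 150 mM, and Gohir.A03G100200.v2.1 reaches 20.5 at 300 mM.

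Most genes that changed between 50 and 150 mM were also changed at 300 mM relative to 50 mM. Of the 8145 genes that rose at 150 mM, 5379 (66.0%) were also higher at 300 than at 50 mM and 160 were lower. Of the 6779 that fell, 4939 (72.9%) were also lower at 300 mM and 10 were higher. Both comparisons use the same 50 mM libraries. Independent lists of these sizes would share 1305 rising and 1102 falling genes. In a simulation all libraries, those at 50 mM included, were redrawn as unchanged, with noise independent between genes. Its comparisons of 150 and 300 mM with the same redrawn 50 mM group shared 0 calls. This follows from unchanged groups giving few calls and does not measure the overlap that shared libraries bring. The fold changes correlated at 0.77 across genes, against 0.502 in the simulation, with a covariance of 0.405 against 0.0278. A shared group of equal size and spread gives about that simulated correlation by design. Deviations of the real 50 mM libraries that run across genes were not part of the simulation. The 3 libraries at 50 mM do not split into parts of at least 2 libraries each, and no split was made, so part of the excess in shared calls may come from the shared libraries.

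The 3 concentrations together gave 18437 genes that differed (36.2%, limma F test). By the order of their group means, 6190 (33.6%) were highest at 150 mM, 4492 (24.4%) fell throughout, 4036 (21.9%) rose throughout and 3719 (20.2%) were lowest at 150 mM. With each library scaled to its recovered reads, 6746 rose throughout, 5663 were highest at 150 mM, 4186 were lowest there and 3031 fell throughout. With upper-quartile scaling 5081 rose and 3722 fell throughout, and 5632 were highest at 150 mM. The largest class, and the order of rising and falling genes, thus depended on the scaling. Without replicates 1 and 2 of the 50 mM group, left out in turn, 2453 and 2425 genes were lowest at 150 mM. Genes highest at 150 mM had a median log2 change of 0.89 from 50 to 150 mM and of -0.44 from 150 to 300 mM. For genes lowest at 150 mM the medians were -0.87 and 0.30. These orders describe the means, and most genes did not pass both steps. The same 150 mM libraries enter both steps, so noise in them favours the orders highest and lowest at 150 mM.

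Both steps passed separately for 972 genes that rose to 150 mM and fell again at 300 mM, and for 217 that fell and rose again. In the genes highest at 150 mM that passed both steps, the median log2 change was 1.01 for the first and -1.21 for the second step. A further 77 genes rose and 226 fell at both steps. With each library scaled to its recovered reads 143 genes rose and 158 fell at both steps, and with the replicate block 52 rose and 124 fell. With no filter on low values 51 rose and 150 fell at both steps, and 128 fell and rose again. The counts also moved with single libraries. Without replicate 1 of the 300 mM group, 1559 genes rose and fell and 732 fell and rose. Leaving out each library in turn gave 413 to 1559 genes that rose and fell, 58 to 732 that fell and rose, 25 to 79 that rose at both steps and 86 to 249 that fell at both. In that library the genes highest at 150 mM had a median level of 0.19 above their own mean on the log2 scale, against -0.09 and -0.12 in the other libraries at 300 mM.

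**Figure D4:**
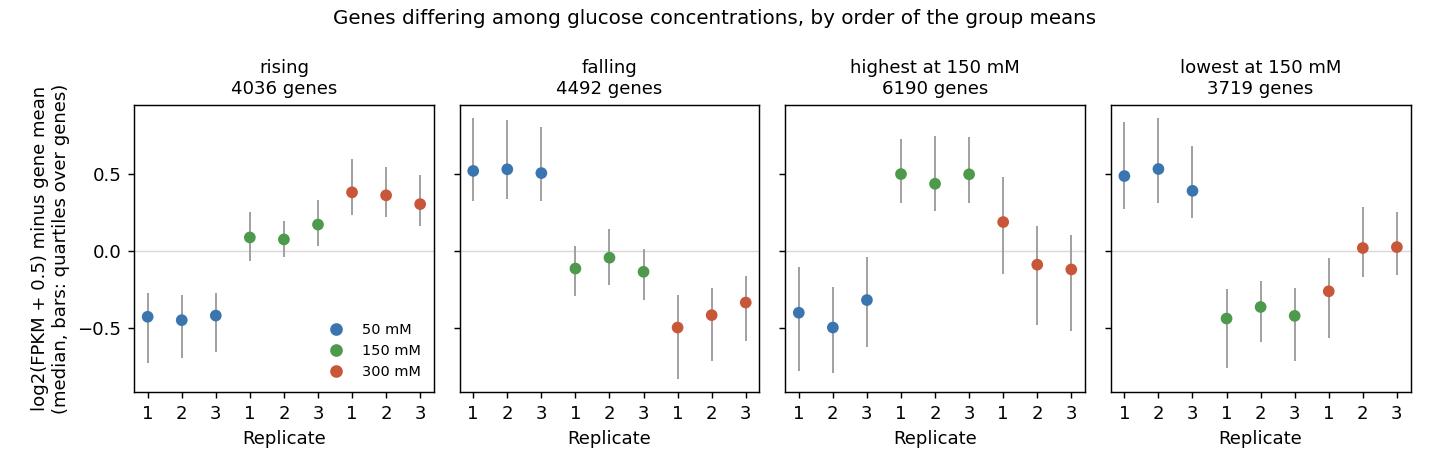
Genes passing the limma F test, in 4 classes by the order of their group means, with the median over genes of log2(FPKM + 0.5) minus the gene's own mean in each library and bars from the lower to the upper quartile over genes. Among the 6190 genes highest at 150 mM, replicate 1 at 300 mM lies at 0.19 and the other libraries of that group at -0.09 and -0.12.

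Upland cotton is an allotetraploid, with an A and a D subgenome from different ancestors. Genes of both subgenomes were called at like rates at every step. From 50 to 150 mM, 7066 of 23051 tested A genes (30.7%) and 7222 of 23811 D genes (30.3%) changed, an odds ratio of 1.01 with a 95% interval of 0.976 to 1.06. The odds ratio was 0.98 (0.91 to 1.06) for 300 against 150 mM and 1.02 (0.979 to 1.06) for 300 against 50 mM. None of 9 Fisher's exact tests of all, higher or lower calls passed, with a lowest adjusted p of 0.814. Genes were taken as independent in these tests and intervals. Reads of an A gene counted at its D copy could make the rates alike, which was not tested for these rates.

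A larger share of the tested genes changed on chromosome D05 than on the rest of the chromosomes in both comparisons with 50 mM. At 150 mM 908 of its 2728 tested genes changed (33.3%, odds ratio 1.15, Fisher's exact adjusted p = 0.0315 over 26 chromosomes), and at 300 mM 1019 changed (37.4%, odds ratio 1.19, adjusted p = 0.000475). On chromosome D02, 152 of 1738 genes (8.75%) changed between 150 and 300 mM (odds ratio 1.41, Fisher's exact adjusted p = 0.00319). No other chromosome passed in any of the 3 comparisons. The comparisons with 50 mM use the same 50 mM libraries, so the D05 results are not independent of each other. Chromosome A05, of the same number in the A subgenome, had odds ratios above 1 as well. They were 1.11 at 150 mM (Fisher's exact adjusted p = 0.109) and 1.08 at 300 mM (adjusted p = 0.597). Whether D05 differed from A05 was not tested. These tests treat genes as independent, which neighbouring genes were not.

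The loci numbered outside the Gohir naming were called less often than Gohir genes. Among 4027 tested numbered loci, 623 (15.5%) changed from 50 to 150 mM against 30.5% of Gohir genes (odds ratio 0.418, 95% interval 0.382 to 0.456, Fisher's exact p = 8.18e-100). From 150 to 300 mM 2.29% changed against 6.43%, and from 50 to 300 mM 17.8% against 33.5%. Their median FPKM was 2.5, against 8.33 for Gohir genes. Of the numbered loci that changed at 150 mM, 39.7% rose, against 55.2% of the Gohir genes that changed (odds ratio 0.533, Fisher's exact p = 2.64e-14). Between 150 and 300 mM the direction was the opposite, with 39.1% of the changed numbered loci higher against 20.9% of the Gohir genes (odds ratio 2.43, Fisher's exact p = 8.71e-05). For 300 against 50 mM, which does not use the 150 mM libraries, the shares were 51.3% and 49.6% (Fisher's exact p = 0.36). The comparisons with opposite directions share the 150 mM libraries, so a trait of those libraries could give both. These tests count loci as independent and do not measure the spread between libraries.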

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

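The alternatives with limma-voom on recovered reads, scaling to recovered reads and results without replicate 1 of the 300 mM group together with that scaling were chosen after seeing the data. Other pseudocounts, filters on low values and scalings left each total of changed genes within 1.5 times its value. No gene called in both a fit of this kind and the fit reported was called in the opposite direction. Counts by direction or order moved further. With scaling to recovered reads 1065 genes were higher for 300 against 150 mM, against 668, and 6746 rose throughout, against 4036. Stricter thresholds lowered the counts by construction. At an adjusted p under 0.01 there were 7824 genes for 150 against 50 mM, 998 for 300 against 150 mM, 8852 for 300 against 50 mM and 9916 for the 3 concentrations together. With a change of at least 2-fold required, the counts were 6142, 1853, 6330 and 8774. The fit of only the 150 and 300 mM libraries called 2002 genes for that comparison. Such fits called 16752 genes for 150 against 50 mM and 14437 for 300 against 50 mM. The fit of all 9 libraries assumes the same spread in each group. Correlations within groups were 0.972 to 0.979 at 50 mM and 0.945 to 0.959 at 300 mM. The 3113 calls for 300 against 150 mM thus rest in part on that assumption, and the cause of the changed counts was not tested. Leaving out each library in turn gave 10448 to 12572 genes for 150 against 50 mM, 1547 to 4395 for 300 against 150 mM, 11872 to 16334 for 300 against 50 mM and 13208 to 18491 for the 3 concentrations, with fewer samples in each fit.

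The replicate numbers in the labels did not pair the samples: same-numbered libraries deviated from their group means with correlations of -0.275 to 0.102, and most libraries correlated best with another number. With the replicate block 12962, 2149 and 14354 genes were called in the 3 comparisons and 15571 for the concentrations together, and 124 genes fell at both steps against 226 without it. Of 192 values of named genes under alternatives, over 12 pairs of gene and comparison, 190 stayed past the threshold in the same direction. The other 2 were the rises of Gohir.A12G273450.v2.1 and Gohir.D12G274150.v2.1 at 300 mM with limma-voom on recovered reads. The named genes were picked from these data for the largest folds already past the threshold with no overlap. Their staying past it was favoured by that choice and does not measure how other calls hold. Not run were the alternatives that need a count table, and every alternative for the gene lists. The subgenome comparison was repeated only with limma-voom calls, and the tests of chromosomes and numbered loci, the overlap of comparisons and the candidate copies were not repeated under the alternatives. Depth limits the lowest genes, as with the 3 reads behind the 150 mM level of Gohir.A12G273450.v2.1.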

Other observations

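Chosen only after the result was seen were the tests of the lower side of the 300 against 150 mM calls by scaling, by replicate 1 of the 300 mM group and by both together, and the test of reads shared between A and D copies. Candidate copies of a gene on the A and D subgenomes changed together. As candidates, 6188 pairs were taken with the same chromosome number, the same coding length (at least 300 bases), a relative position within 2% of the chromosome's gene order and at least 100 reads each. Pairing was by these properties and not by sequence. From 50 to 150 mM both members passed in 1196 pairs, where independent calls would give 634.8, and 1147 of these (95.9%) changed in the same direction while 49 changed in opposite directions. From 150 to 300 mM both passed in 223 pairs, 221 of them in the same direction, against 29.7 for independent calls. In 1572 pairs only 1 member passed from 50 to 150 mM, which does not show that the members differed, since the difference was not tested.

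The log2 changes of the candidate pairs from 50 to 150 mM correlated at 0.681 across pairs. Pairs of unlike coding length, drawn from within the same 2% of the gene order, reached at most 0.0364 in 100 draws. The draws were not matched to each candidate pair's own distance. Neighbouring genes on the same chromosome correlated at 0.0984 for this comparison. These values argue against position alone. Reads of 1 copy counted at the other could make both move together. An earlier form of this test compared pairs at least 4-fold apart in FPKM (0.448) with unlike-length pairs (at most 0.17), and it was dropped because a weaker copy fed by its partner's reads would follow that partner too. Among pairs with at least 1000 reads for each copy, those at least 4-fold apart correlated at 0.651 (84 pairs) and those within 2-fold at 0.795 (3709 pairs). The difference was -0.144 with a 95% bootstrap interval of -0.342 to 0.00474, so shared reads and a shared response of the copies cannot be told apart here.

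Most genes that changed between 150 and 300 mM fell, and 21.5% were higher. With each library scaled to its recovered reads the share was 34.9%, and without replicate 1 of the 300 mM group it was 30.8% (12.99% to 18.5% without any other library of these groups), so neither change alone brought it to the 45% set as a bound. A smaller share of rises than of falls was called, 42.1% of higher and 72.8% of lower genes with a change of at least 2-fold (median SE 0.368 and 0.303), but before any test only 27.3% of these genes were higher, which argues against spread as the whole cause. With the scaling and the omission together 4598 genes were called and 44.2% were higher, close to that bound. That scaling moves the median log2 change of all genes from -0.00455 to 0.0725 and so raises the share by construction, and which scale is right was not tested, so an effect of the scaling and that library together and a true excess of falls at 300 mM both stay open.

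The numbered loci were called less often than Gohir genes, which their lower abundance might explain, but matching on abundance left the gap. Gohir genes drawn to match their FPKM and reads were called in 28.3% of cases from 50 to 150 mM (26.8% to 30.2% in 100 draws), against 15.5% of the numbered loci. For 300 against 150 mM the matched share was 4.55% against 2.29%, and for 300 against 50 mM 28.8% against 17.8%. What the loci are was not tested, and the design offers no biological explanation for the gap.

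Neighbouring genes were called in the same direction in 2878 pairs from 50 to 150 mM, against a mean of 2205 and a highest value of 2306 in 200 shuffled orders. The largest Spearman correlation of fold change with coding length was -0.0818 across genes, for 300 against 150 mM.

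Other splits of the samples were counted for each comparison. For each pair of concentrations the real split was 1 of 10 splits of 6 libraries into groups of 3 and gave the most genes: 14924 against a highest other of 0 for 150 against 50 mM, 3113 against 15 for 300 against 150 mM and 16456 against 0 for 300 against 50 mM. Each other split mixes the concentrations compared, so their difference adds to the spread within groups and lowers the count. The gaps in counts follow in part from this and do not show how many calls unchanged libraries would give. With 10 splits the share cannot fall under 0.05. For the 3 concentrations together, 1 of 100 drawn splits (of 280) reached 18437 genes, the real one, a share under 0.05. This share takes the libraries as independent, which the labels do not state. A difference between the groups other than glucose would give the same rank. The highest other split gave 11095 genes and kept the 50 mM libraries together while mixing those at 150 and 300 mM. The median of the other splits was 0, and mixing of concentrations lowers these counts as well.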
